A study of Mus musculus with 16 samples.

How the data were processed

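Gene expression was measured by bulk RNA sequencing in 16 samples of mouse skin cells, sorted by CD45 into an immune and a stromal fraction and taken 6 h after hypobaric pressure or from unstretched skin. Per the labels' protocols, cDNA was made with the SMART-Seq mRNA LP kit and libraries with Nextera XT. Per the submitters' processing notes, reads were checked with FastQC 0.11.9 and aligned with STAR, whose version is not given, to the mouse build mm10. The table deposited by the authors holds raw counts per Ensembl gene for the 16 libraries, with no normalization. The counting tool, the strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here.

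The table has 55487 gene IDs, of which 55394 matched the GENCODE M21 annotation (GRCm38, the same assembly as mm10) that supplied symbols, coordinates, transcript length and GC content. Of 108 symbols shared by several IDs, the ID with the most reads kept the symbol. In all, 44374 genes had a read in at least 1 library. Each column of the table was matched to a sample by the description in its label, and 0 columns were left without a sample. Total counts ranged from 2645421 to 26944965 per library. PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only. Pairs of libraries within a group differed by 28.1 to 280.1 chi-square per degree of freedom, so no library was a copy of another in its group.

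Samples were grouped by the sorted fraction and the treatment in the labels, 4 per group. The 4 comparisons were stretched against control in the stromal and in the immune fraction, the difference of these 2 effects, and immune against stromal in the controls. Each used the libraries of its own groups in edgeR 4.0.16 under R 4.3.3, with filterByExpr (minimum count 10, minimum total count 15), TMM scale factors and the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values of single genes are TMM-scaled, while CPM sums over a list or over the receptor genes are scaled to the library total. Standard errors of log2 fold changes were derived from the F statistic. No covariate entered the model.

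A set of 40 gene lists for skin cell types, immune cell types, stress responses and signalling pathways was fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated for each list. Fry was run beside it. It tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Overlap between the fractions was tested with the two-sided Fisher's exact test.

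The comparisons and tests were fixed then too, as was the named-gene rule. It took *Ptprc* for the sort, and up to 10 genes that rose and 10 that fell with the largest absolute log2 fold change. These had to be called, to have all 4 libraries of 1 group above the 4 of the other, and to have a mean CPM of at least 10 in the higher group. Predicted genes without a name, pseudogenes marked as such in their symbol, and immunoglobulin and T cell receptor segments were left out. Where under 5 genes passed, the 10 with the smallest p were named as values that did not pass. Up to 4 members of each list with the smallest p could be named, and the text uses a subset of these. *Mafk* in the stromal fraction was named outside the rule.

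The alternatives also fixed then were RLE and upper-quartile scale factors, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a stricter filter (at least 50 reads in at least 4 libraries), glmTreat with a fold minimum of 1.5, the number of detected genes as a covariate, all 16 libraries in 1 fit, the title number as a block, and the omission of each library in turn. Added after the data were seen were offsets that remove a smooth trend on transcript length and GC content in each library (natural splines with 4 degrees of freedom, prior count 2), the exclusion of libraries with receptor-gene reads or many neutrophil transcripts, and thinning of the immune libraries to the depth of the shallowest. Splits of the libraries into groups of the same size were tested, the real one included: all 35 for 8 libraries and 100 for the difference of effects.

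The tests were also tested on simulated counts with the libraries' depths and spread. In the stromal design 16.4% of the genes changed 2-fold and 81.8% of those changed 4-fold were recovered. In the immune design 0% and 39.4% were recovered, in the difference of effects 0% and 18.2%, and in the sort comparison 0% and 36.4%. False calls were 1 of 66, 3 of 29, 0 of 12 and 2 of 26 calls. Few genes were changed in each simulation, so the recovered shares are not the sensitivity of a comparison in which many genes differ. No reads were realigned, and no library was left out of the reported values.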

Results

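RNA was sequenced in bulk from mouse skin cells 6 h after hypobaric pressure, a suction that stretches the skin, and from cells of unstretched skin as the control. The cells had been sorted on CD45, the pan-leukocyte surface protein encoded by *Ptprc*, into a CD45-positive (immune) and a CD45-negative (stromal) fraction. The 16 libraries formed 4 groups of 4 (stromal control, stromal stretched, immune control and immune stretched). Total counts per library ranged from 13563586 to 20467010 in the stromal controls and from 21955174 to 26944965 in the stretched stromal libraries. They ranged from 2645421 to 6662268 in the immune controls and from 7018743 to 20095580 in the stretched immune libraries. Depth therefore differed between stretched and control libraries in each fraction, without overlap. Reads on 1972 olfactory and vomeronasal receptor genes, which are transcribed mainly in sensory neurons, amounted to 6209 CPM (counts scaled to the library total) in immune control 4, 424 in stretched stromal library 7 and 208 in stretched stromal library 8. The other libraries held 17.96 to 69.9 CPM on these genes. The same 3 libraries detected 35303, 35821 and 32977 genes, against 20429 to 25955 in the others. Libraries are named by the numbers in their titles, which are 1 to 4 and 5 to 8 for the stromal controls and stretched samples. The labels do not say whether the samples are separate animals, so the p-values measure only the spread between these samples.

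**Figure D1:**
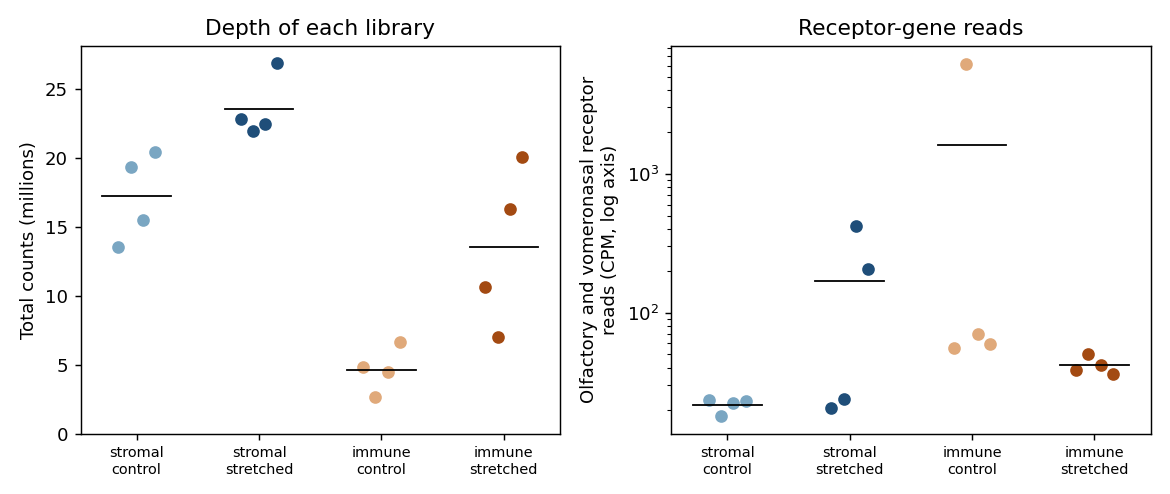
Total counts (left) and CPM on olfactory and vomeronasal receptor genes on a log axis (right) for the 4 libraries of each group, with lines at the group means. Immune control 4 reached 6209 CPM on the receptor genes, and stretched stromal libraries 7 and 8 reached 424 and 208 CPM.

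The stretched and control stromal fractions were compared to ask which transcripts of non-immune skin cells differ 6 h after stretching. The called genes had adjusted p values between 0.0363 and 0.05 in the edgeR test. Each of the 45 stromal genes named and called lost its call under 11 to 15 of 21 alternatives. *Thbs1* (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133, GRCm38), which encodes the matrix glycoprotein thrombospondin-1, rose from 575 ± 221 to 1297 ± 122 CPM (SD, n = 4 per group), a log2 fold change of 1.17 ± 0.27 (SE). *Icam1* (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817), an adhesion molecule for leukocytes, rose from 587 ± 156 to 1206 ± 146 CPM, a log2 fold change of 1.04 ± 0.23. *Gja1*, the gap junction protein connexin 43, rose from 549 ± 49.1 to 1170 ± 184 CPM (log2 fold change 1.09 ± 0.19), with each stretched library above each control. The ribosomal protein gene *Rplp1* fell from 519 ± 154 to 208 ± 66.6 CPM (log2 fold change -1.32 ± 0.31). *Tnc* (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), which encodes the matrix protein tenascin-C, rose from 8.26 ± 2.90 to 47.0 ± 49.4 CPM, with 119.7 CPM in stretched library 5. Its log2 fold change was 2.502 ± 0.62 with all libraries and 1.45 without stretched library 5.

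**Figure D2:**
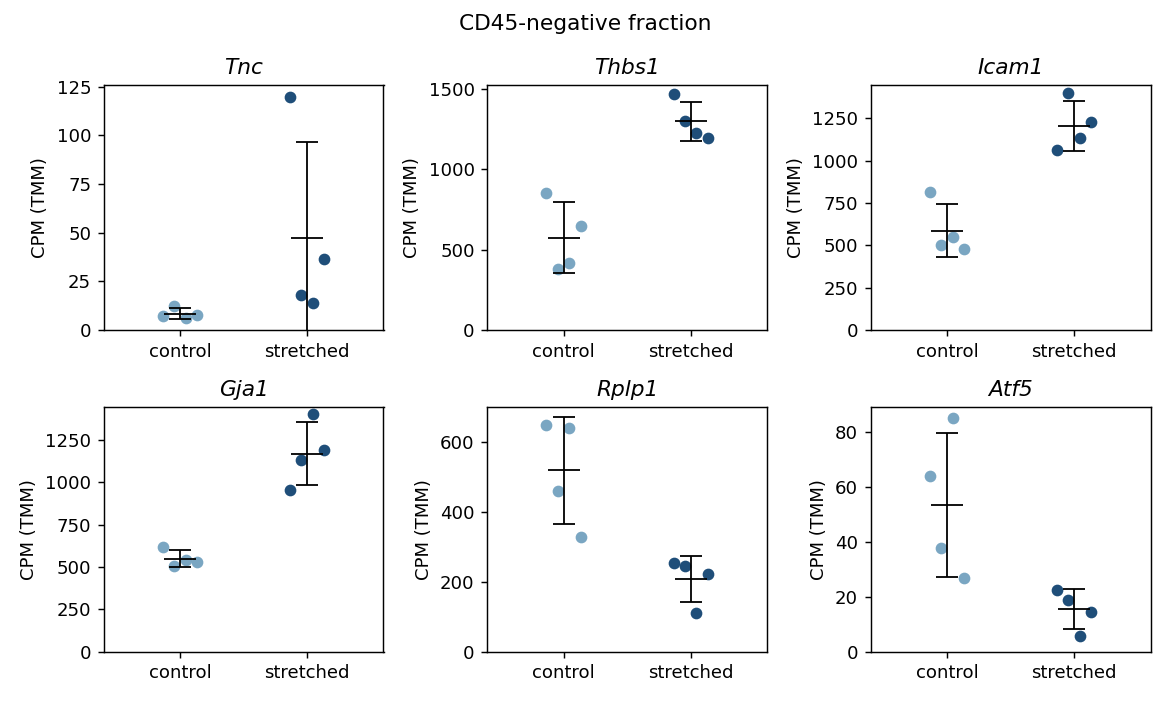
TMM-scaled CPM of 6 genes in the 4 control and 4 stretched libraries of the stromal fraction, with the mean and SD of each group. *Tnc*, *Thbs1*, *Icam1* and *Gja1* lay higher and *Rplp1* and *Atf5* lower in each stretched library than in each control.

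Among the other genes that rose by the named-gene rule were *Mybpc1* (1.97 ± 0.38), *Mybpc2* (1.85 ± 0.38) and *Pygm* (1.62 ± 0.33), which encode slow and fast myosin-binding protein C and muscle glycogen phosphorylase. *Stc1*, the secreted glycoprotein stanniocalcin-1, rose by 1.75 ± 0.44, and *Ahrr*, the repressor of the aryl hydrocarbon receptor, by 1.80 ± 0.35. *Pcdhgc3* (1.93 ± 0.29), *Leng8* (1.89 ± 0.31), *Smcr8* (1.71 ± 0.22) and *Rnf24* (1.59 ± 0.28) also rose. *Atf5*, a transcription factor of the integrated stress response, fell from 53.4 ± 26.4 to 15.4 ± 7.21 CPM (log2 fold change -1.79 ± 0.44). *Sec61b*, a subunit of the protein translocation channel, fell with a log2 fold change of -1.38 ± 0.32, and *Map1a*, which binds microtubules, with -1.37 ± 0.31. *Cdc42ep2* (-1.40 ± 0.24), *Mn1* (-1.39 ± 0.29), *Tppp3* (-1.36 ± 0.30) and *Cmc2* (-1.36 ± 0.21) fell as well. The lower genes also included *CT010467.1*, an annotated ribosomal RNA on chromosome 17 (-2.14 ± 0.44), whose reads cannot be assigned with certainty among repeated ribosomal RNA copies. *Abhd11os* (-1.47 ± 0.31) and *Mir703* (-1.44 ± 0.32) fell too, but with no strand setting given their reads cannot be told from those of overlapping transcripts.

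NF-kB target genes rose as a list in the stretched stromal fraction (median log2 fold change 0.57, 21 of 23 positive, camera adjusted p = 4.84e-05; adjusted p = 0.390 with an estimated correlation). Of these, 4 rose over all genes and 11 when adjusted over the list alone. They were *Icam1*, *Nfkb2* (1.07 ± 0.25), the NF-kB inhibitor *Tnfaip3* (0.89 ± 0.21) and the adhesion molecule *Vcam1* (0.73 ± 0.17). Cell junction genes rose as a list (median 1.33, 23 of 24 positive, camera adjusted p = 9.57e-08; adjusted p = 0.872 with an estimated correlation), with *Gja1* as the member that rose over all genes and 6 members adjusted over the list alone. Mechanosensitive channels rose as a list (median 0.60, camera adjusted p = 0.0115; adjusted p = 0.872 with an estimated correlation). The polycystins *Pkd1* (1.15 ± 0.25) and *Pkd2* (0.88 ± 0.18) were the 2 of its 13 members that rose, and also the 2 adjusted over the list alone. The list's call ended without stromal control 2 (adjusted p = 0.0600) or stromal control 4 (adjusted p = 0.121), with length and GC offsets (median 0.29, adjusted p = 0.0645) and without stretched libraries 7 and 8 (median 0.20, adjusted p = 0.0630). Of 27 cytoskeleton and focal adhesion genes, 3 rose and 1 fell, over all genes and adjusted over the list alone, and the list did not pass camera (adjusted p = 0.235). These were the fibronectin receptor subunit *Itga5* (301 ± 45.8 against 151 ± 41.0 CPM), the adaptors *Vcl* (1.04 ± 0.24) and *Pxn* (0.70 ± 0.16), and the myosin light chain *Myl9* (-0.99 ± 0.22). The value of *Vcl* was -0.050 with the title number as a replicate block over all 16 libraries. No number occurs in both stromal groups, so that value rests on a comparison with immune libraries of the same numbers. *Csf3*, the granulocyte growth factor, rose by 1.61 ± 0.36, from 3.25 ± 1.49 to 9.89 ± 3.44 CPM, the 1 of 16 cytokine and alarmin genes that rose (1 higher and 1 lower adjusted over the list alone).

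Ribosomal protein genes fell as a list: 34 of 34 had negative values, with a median log2 fold change of -0.97 (camera adjusted p = 1.51e-21; adjusted p = 0.872 with an estimated correlation). Of them 14 fell over all genes and 33 adjusted over the list alone, among them *Rpl23* (-1.16 ± 0.26), *Rps29* (-1.12 ± 0.25) and *Rps4x* (-1.12 ± 0.27). Reads of these genes are hard to tell from those of their many pseudogenes. Stretch fold changes rose with transcript length across genes, which are not independent replicates (Spearman rho 0.42), and ribosomal protein transcripts are short. Their list median was -0.64 with length and GC offsets.

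Marker genes of other cell types also moved in the stretched stromal fraction. Hair follicle genes rose as a list (median 0.90, camera adjusted p = 0.00268; adjusted p = 0.872 with an estimated correlation), with 3 of 13 members rising over all genes and 5 adjusted over the list alone. The hair keratin *Krt35* was 15.4 ± 22.6 CPM against 0.476 ± 0.522 (log2 fold change 5.06 ± 1.28), and 3.18 without stretched library 8, where the gene's call also ended. *Tchh*, trichohyalin of the inner root sheath, rose from 0.716 ± 0.213 to 4.03 ± 2.86 CPM. *Lrig1*, a stem cell marker of the follicle that is also a member of the fibroblast marker list, rose by 1.06 ± 0.23 on the log2 scale. The hair follicle list median was 0.47 without stretched library 8 and 1.37 without control 1. Skeletal muscle markers rose as a list (median 0.58, camera adjusted p = 0.00268; adjusted p = 0.872 with an estimated correlation), summing to 2185 ± 627 CPM against 1326 ± 505 CPM. *Myh1* (2.34 ± 0.56) and *Atp2a1* (2.01 ± 0.48) were the 2 of 18 that rose, with 6 adjusted over the list alone, and the list did not pass without stretched library 5 (median 0.35, adjusted p = 0.117). Basal keratinocyte markers rose as a list (median 0.84, camera adjusted p = 0.00962; adjusted p = 0.872 with an estimated correlation) with 0 of 14 members past the edgeR test over all genes or over the list alone. Its member *Col17a1* had a value of 1.99 ± 0.62 (adjusted p = 0.0759), and the list median was 1.41 without control 1 and 0.55 without stretched libraries 7 and 8. Blood endothelial markers rose as a list (median 0.63, camera adjusted p = 0.0115; adjusted p = 0.872 with an estimated correlation) with 0 of 19 members past the test. That call ended without control 4 (adjusted p = 0.165) or stretched library 6 (adjusted p = 0.0755), and without stretched libraries 5 and 6 together (adjusted p = 0.2997).

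Over all genes, 800 of 16074 tested passed in the stromal fraction (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 329 higher and 471 lower after stretch. The smallest adjusted p was 0.0363, 4309 genes had an unadjusted p under 0.05 where chance gives 804, and the 2 groups did not overlap in 2903 genes (18.1%, against a chance share of 2.86%). The count was 0 without control 1, 2 or 3 or stretched library 7 or 8, 2 without stretched library 6, 719 without control 4 and 1589 without stretched library 5, and it was 0 without stretched libraries 7 and 8 together. DESeq2 called 2312 genes and limma-voom 3599, while edgeR called 4 with length and GC offsets, 1 with the number of detected genes as a covariate and 0 with all 16 libraries in 1 fit.

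The stretched and control immune fractions were compared to ask which transcripts of skin leukocytes differ 6 h after stretching. MHC class II antigen presentation genes rose as a list (median log2 fold change 1.14, 11 of 12 positive, camera adjusted p = 3.03e-05; adjusted p = 0.915 with an estimated correlation), with 0 members past the edgeR test over all genes or over the list alone. *Cd74* (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, was 17007 ± 5854 CPM in stretched and 5549 ± 2193 CPM in control libraries (n = 4 per group). Its log2 fold change was 1.62 ± 0.53, higher in 4 of 4 stretched libraries than in any control, with an adjusted p of 0.198. The peptide loading genes *H2-DMb1* (1.28 ± 0.43), *H2-DMb2* (1.17 ± 0.37) and *H2-DMa* (1.24 ± 0.43) had values of the same sign. So did *Mgl2* (1.74 ± 0.53) and *Cd209a* (1.61 ± 0.49), lectins of dermal dendritic cells and macrophages, with adjusted p of 0.185 each. The class II list kept its camera call in each of the 8 omissions of 1 library. Its reads summed to 22046 CPM in stretched library 2, below immune controls 5 and 6 (24131 and 25124 CPM). The other stretched libraries held 44506 to 63207 CPM, above each control.

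NF-kB targets rose as a list in the immune fraction (median 0.45, 17 of 24 positive, camera adjusted p = 0.0407; adjusted p = 0.915 with an estimated correlation), with 0 members past the test over all genes and 1 adjusted over the list alone. *Bcl3* had a value of 1.48 ± 0.35 (221 ± 51.9 against 79.2 ± 33.5 CPM), *Relb* 0.76 ± 0.25 and the maturation marker *Cd83* 1.21 ± 0.48. This call ended without control 3 (adjusted p = 0.118), control 4 (0.216), control 6 (0.0786) or stretched library 2 (0.266), and the median was 0.26 without control 4 and 0.15 without stretched library 2. The call also ended with length and GC offsets (median 0.28, adjusted p = 0.0837) and without control 4 and stretched library 2 together (median 0.016, adjusted p = 0.660). Ribosomal protein genes fell as a list (median -0.37, camera adjusted p = 0.000501; adjusted p = 0.915 with an estimated correlation), with 0 members past the test over all genes and 3 lower adjusted over the list alone. *Rplp2* had a value of -1.59 ± 0.35 and *Rplp1* of -1.53 ± 0.35, and the list did not pass without control 3 (median -0.12, adjusted p = 0.105), while its median was -0.70 without control 4 and stretched library 2 together. Fibroblast markers rose as a list (median 0.74, camera adjusted p = 0.0112; adjusted p = 0.915 with an estimated correlation), with *Sfrp2* at 2.34 ± 0.72 and *Col3a1* at 1.27 ± 0.50. The fibroblast call ended without control 5 (adjusted p = 0.0511) or control 6 (0.0677), and the median was 1.13 without control 4 and stretched library 2 together.

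Lymphatic endothelial markers fell as a list in the stretched immune fraction (median -1.05, camera adjusted p = 0.00739; adjusted p = 0.915 with an estimated correlation). *Pdpn* had a value of -1.05 ± 0.42 and *Nts* of -1.14 ± 0.46, and the call ended without control 3 (median -0.59, adjusted p = 0.161) or stretched library 2 (0.114). Blood endothelial markers fell as a list (median -0.82, camera adjusted p = 0.0407; adjusted p = 0.915 with an estimated correlation). *Cdh5*, VE-cadherin, was 19.2 ± 9.23 CPM in stretched and 79.6 ± 59.4 CPM in control libraries (-2.05 ± 0.54, adjusted p = 0.156), and *Kdr* had a value of -1.07 ± 0.46. The blood endothelial call ended without control 3 (adjusted p = 0.271), control 4 (0.223), control 6 (0.0762) or stretched library 2 (0.393). Its median was -0.41 without control 3, -0.44 without control 4 and -0.54 without stretched library 2. Without control 4 and stretched library 2 together, neither the blood endothelial (median -0.32, adjusted p = 0.767) nor the lymphatic list (adjusted p = 0.192) passed. Red blood cell genes rose as a list (median 0.90, camera adjusted p = 0.0407; adjusted p = 0.915 with an estimated correlation), and did not pass without control 4 (adjusted p = 0.103) or stretched library 1 (0.0921). None of the fibroblast, endothelial or red blood cell list members passed the test over all genes or adjusted over the list alone. Neutrophil marker reads summed to 55662 CPM in stretched library 2 and to 1885 to 3195 CPM in the other stretched libraries, against 3067 to 17827 CPM in the controls, and the list did not pass (median 1.01, mean 1.03, but camera direction down, adjusted p = 0.694).

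Of 14183 genes tested in the immune fraction, 0 passed (edgeR quasi-likelihood test, Benjamini-Hochberg), with a smallest adjusted p of 0.134. At an unadjusted p under 0.05 there were 2467 genes where chance gives 709, and the 2 groups did not overlap in 1683 genes (11.9%, against a chance share of 2.86%). The genes with the smallest p, none of which passed, included *Mafk* (1.76 ± 0.25, 118 ± 18.4 against 34.9 ± 8.79 CPM), a small Maf transcription factor, and *Lce1m* (1.64 ± 0.24), a cornified envelope gene. *Coro1b* (2.43 ± 0.38), *Naa60* (2.70 ± 0.43), *Tm9sf1* (1.44 ± 0.23), *Oaf* (1.84 ± 0.33), *Tspan31* (1.52 ± 0.27) and *G6pdx* (2.04 ± 0.37) had positive values, and *Pelp1* (-1.75 ± 0.30) and *Wdr89* (-1.89 ± 0.33) negative ones. DESeq2 called 781 genes, limma-voom 888 and edgeR with all 16 libraries in 1 fit 667. The edgeR count was 45 without stretched library 2 and 21 without control 4 and stretched library 2 together.

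**Figure D3:**
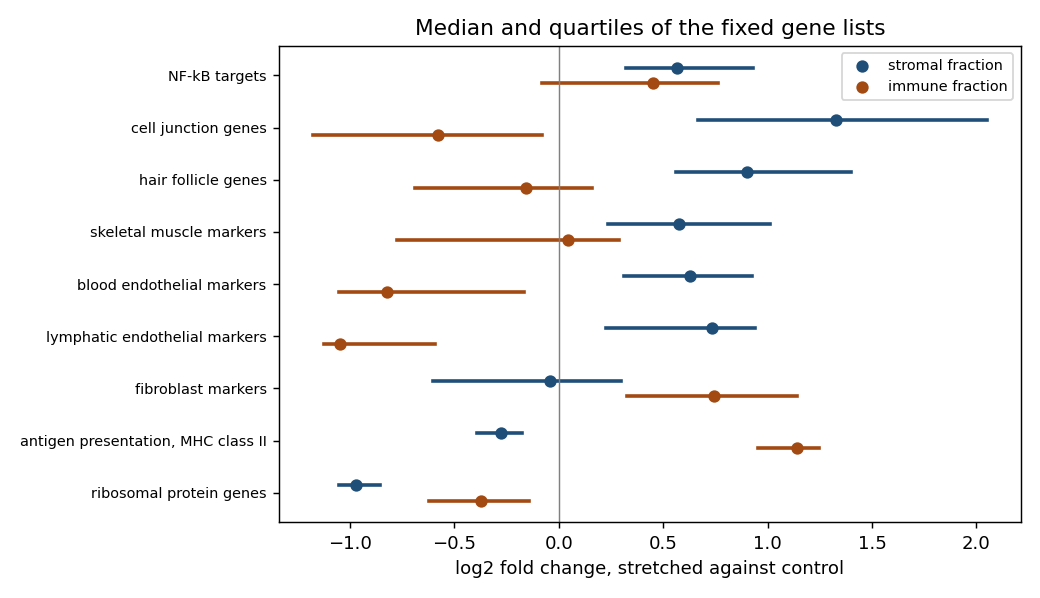
Median (point) and quartiles (line) of the log2 fold change, stretched against control, of the measured members of 9 gene lists in the stromal and immune fractions. Ribosomal protein genes had medians of -0.97 and -0.37, and MHC class II genes had medians of -0.28 and 1.14.

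The stretch effect in the immune fraction was compared with that in the stromal fraction through the difference of their log2 fold changes, so that positive values mean a more positive effect in immune cells. Cell junction genes (median -1.63), hair follicle genes (-2.77) and basal keratinocyte markers (-1.51) were lower in this difference as lists, with camera adjusted p of 4.65e-05, 0.00245 and 0.00877. Blood endothelial (-1.34, adjusted p = 0.00192) and lymphatic endothelial markers (-1.32, adjusted p = 0.00877) were lower too. Ribosomal protein genes (0.73, adjusted p = 4.65e-05), fibroblast markers (1.05, adjusted p = 0.0249) and red blood cell genes (2.0, adjusted p = 0.0245) were higher. None of these 8 lists passed with an estimated correlation (adjusted p = 0.975 at the lowest), and each had 0 members past the edgeR test over all genes. Adjusted over the list alone, 4 hair follicle genes and 3 lymphatic endothelial markers were lower. The difference tested 18 hair follicle and 27 cell junction genes, against 13 and 24 in the stromal fit and 6 and 15 in the immune fit. Their medians thus include members with too few reads to be tested in the immune fraction. *Cdh5* had a difference of -2.03 ± 0.69, the lymphatic receptor *Flt4* -2.30 ± 0.73, *Sfrp2* 3.54 ± 1.08 and *Rpl4* 1.18 ± 0.42. The basal keratinocyte call ended without immune control 3 (adjusted p = 0.473), immune stretched library 2 (0.0613) or stromal control 4 (0.0772). The blood endothelial call ended without immune control 3 (0.0646), and the lymphatic call without immune control 3 (0.176) or stromal stretched library 5 (0.0718). The fibroblast call ended without immune control 5 or 6 or immune stretched library 7 or 8 (0.0503 to 0.0776). The red blood cell call ended without immune control 6, immune stretched library 1, 7 or 8, or stromal stretched library 5, 7 or 8 (0.0581 to 0.0880). The hair follicle median was -1.78 without immune control 4 and -4.15 without stromal control 2, and the cell junction median -3.08 without stromal control 1. The red blood cell median was 1.21 without stromal control 2 and 3.67 without stromal stretched library 6, and the ribosomal protein median 0.48 without immune stretched library 2 and 0.49 without stromal control 1. The ribosomal protein call ended with length and GC offsets (median 0.40, adjusted p = 0.0621). Without the 3 libraries with receptor-gene reads, the calls of ribosomal protein genes (median 0.27, adjusted p = 0.485), hair follicle genes (-0.78, adjusted p = 0.221), red blood cell genes (0.79, adjusted p = 0.487) and basal keratinocyte markers (adjusted p = 0.0634) ended.

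No gene differed in its stretch effect past the threshold (0 of 18295, edgeR quasi-likelihood test, smallest Benjamini-Hochberg adjusted p = 0.0573), with 4232 genes at an unadjusted p under 0.05 where chance gives 915. The smallest p values belonged to *Naa60* (2.81 ± 0.44), *Tubb4a* (3.40 ± 0.55), *Coro1b* (2.76 ± 0.48), *Dnal4* (2.33 ± 0.41), *Yipf3* (2.02 ± 0.36), *Uck1* (2.26 ± 0.40), *Mif4gd* (2.16 ± 0.39), *Slc25a11* (1.61 ± 0.29), *Pgam1* (2.81 ± 0.51) and *Orai1* (1.88 ± 0.35). *Naa60*, an N-terminal acetyltransferase, averaged 2.09 ± 1.10 CPM in immune controls, 15.5 ± 3.40 in immune stretched, 17.6 ± 2.96 in stromal controls and 17.9 ± 1.87 in stromal stretched libraries. DESeq2 called 1625 genes (735 higher and 890 lower), limma-voom 1453 (1130 and 323) and edgeR without a filter 3924 (397 and 3527). Without a filter the median difference of all genes was -1.14. The edgeR count was 1495 without immune control 6, 114 without immune stretched library 2 and 29 without immune control 4.

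The stretch calls of the 2 fractions shared 0 genes, because 0 passed in the immune fraction. At an unadjusted p under 0.05, 313 of the 13127 genes tested in both fractions were lower in both, against 189 expected for independent lists (odds ratio 2.06, two-sided Fisher's exact test p = 1.95e-22). Genes higher in both numbered 143 against 153 expected (p = 0.365, same exact test). The fractions shared no libraries, but genes are not independent replicates. Stromal fold changes also rose with transcript length across genes (Spearman rho 0.42). The overlap was not repeated with length and GC offsets, so a length trend shared by the fractions stays open. Log2 fold changes of the fractions were hardly related across genes (Pearson r = -0.04, Spearman rho = -0.03). Of the 762 stromal calls tested in the immune fraction, 452 (59.3%) had the same sign there, against 47.5% of all genes. *Mafk*, chosen after its values were seen, was separated in both fractions (1.07 ± 0.18 stromal and 1.76 ± 0.25 immune), as was *Rplp1* (-1.32 ± 0.31 and -1.53 ± 0.35).

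The immune and stromal controls were compared to describe what the sort separated in unstretched skin. *Ptprc* (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708), the sort marker, was 452 ± 191 CPM in the immune and 0.538 ± 0.566 CPM in the stromal controls, a log2 fold change of 9.68 ± 0.79 (adjusted p = 7.04e-06). MHC class II genes were higher in the immune controls in 11 of 11 members (median log2 fold change 7.64), with *H2-Aa* at 8.05 ± 0.64 and *H2-Eb1* at 7.67 ± 0.59. Macrophage genes *Mrc1* (8.37 ± 0.57) and *Pf4* (8.47 ± 0.63), the mast cell protease *Mcpt4* (9.45 ± 0.73), the T cell receptor constant gene *Trbc1* (9.01 ± 0.62) and the cytotoxic granule gene *Gzma* (10.53 ± 0.95) were also higher. *Gzmc*, *Tarm1*, *Lilra6*, *Mmp12*, *Ctla4* and *Cd180* had no read in the stromal controls and were at least 438-fold to at least 714-fold higher in the immune controls, against a floor of 3 reads over the group. *Cd207*, langerin of Langerhans cells, had no stromal control read either and averaged 32.8 ± 55.0 CPM in the immune controls, with 115 CPM in immune control 3. The neutrophil genes *S100a9* (2539 ± 2396 against 1.06 ± 1.83 CPM) and *Retnlg* (183 ± 218 against 0.0709 ± 0.142 CPM) were higher, as was the Fc receptor *Fcgr4* (59.1 ± 38.3 CPM), with 1 read in the stromal controls.

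Fibroblast markers were lower in the immune controls in 18 of 20 members (median -3.48; 19 adjusted over the list alone), with *Pi16* at -4.58 ± 0.43 and *Clec3b* at -4.12 ± 0.33. Collagens and matrix genes were lower in 23 of 26 and higher in 1 (median -3.37; 23 lower and 1 higher adjusted over the list alone), with *Postn* at -4.94 ± 0.35 and *Col6a1* at -4.92 ± 0.36. The largest negative changes by the named-gene rule were those of *Wnt2* (-6.73 ± 0.82), *Cnmd* (-6.32 ± 1.28), *Fgf18* (-5.91 ± 0.82), *Osr1* (-5.89 ± 0.56), *Tubb4a* (-5.84 ± 0.38), *Spon2* (-5.79 ± 0.50), *Tmeff2* (-5.73 ± 0.37), *Sfrp2* (-5.71 ± 0.79), *Cd248* (-5.64 ± 0.47) and *Agtr2* (-5.63 ± 0.82). Endothelial markers were higher in the immune controls: 11 of 19 blood endothelial (12 adjusted over the list alone) and 7 of 10 lymphatic endothelial markers (7 adjusted over the list alone) passed in that direction, and 2 blood endothelial markers were lower (2 adjusted over the list alone). *Cdh5* was 80.1 ± 59.1 against 2.39 ± 1.16 CPM (5.07 ± 0.60), *Pecam1* 3.44 ± 0.49, *Reln* 4.30 ± 0.46 and *Prox1* 3.46 ± 0.39. Red blood cell genes were lower in 6 of 7 (median -3.46), with *Hbb-bs* at -3.60 ± 0.53, and mitochondrially encoded genes were higher in 13 of 13 (median 2.56, or 1.45 with length and GC offsets), with *mt-Rnr1* at 3.26 ± 0.48. In all, 7484 of 15142 genes differed (4027 higher and 3457 lower in the immune controls; edgeR quasi-likelihood test, Benjamini-Hochberg, smallest adjusted p = 2.47e-06). Camera called 19 lists higher and 4 lower, and 0 with an estimated correlation (adjusted p = 0.151 at the lowest), while fry called 24.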

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

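The tests of libraries 7 and 8, of transcript length and GC content, and of the share of dendritic cells and macrophages were chosen after the results were seen, as were the split counts for the stromal fraction and the difference of effects at an unadjusted p and the thinning of the immune libraries.

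The 800 genes called in the stretched stromal fraction were matched by 1 of the 35 splits of the 8 libraries, the real one, and the highest other split gave 1, but with 1 library left out the count was 0 to 1589, so it leaves chance open. Reads from genomic DNA in stretched libraries 7 and 8, a candidate explanation from their 424 and 208 CPM on receptor genes against 17.96 to 23.3 CPM in the stromal controls, stay open: 0 genes were called without these libraries, 3105 without libraries 5 and 6, and 1 with the number of detected genes as a covariate. Without libraries 7 and 8 the median log2 fold change of the called genes in the called direction was 0.84 (quartiles 0.71 to 1.02), against 0.995 with all libraries, but the genes were chosen with both included, so this decides nothing. A bias from transcript length or GC content also stays open: offsets that remove these trends gave a median of 0.73 (quartiles 0.58 to 0.95), all 800 genes kept their direction and 781 an unadjusted p under 0.05, but 4 calls remained, where the adjusted p values had lain between 0.0363 and the threshold and the genes at an unadjusted p under 0.05 went from 4309 to 3419. An effect of stretch itself, which the design names, stays among the open explanations, and the labels give no batch.

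Ribosomal protein genes were lower in the stretched stromal fraction by a median log2 fold change of -0.97. Lower counts of short transcripts stay open as an explanation of part or all of this. Random lists matched on transcript length and expression had a median of -0.65, and 95% of them lay between -0.79 and -0.48. Ribosomal protein genes move together, with an estimated correlation of 0.85. The range of the random lists does not reflect this, so it cannot tell part from all. Reads shared with pseudogenes stay open: 94 tested ribosomal protein pseudogenes had a median of -0.997 (quartiles -1.18 to -0.79), 91 of them negative, and since shared reads would move them with their parent genes this fall decides nothing, although the test had been set up to look for a rise. Mitochondrially encoded genes had 0 of 13 values positive in the same comparison and did not pass as a list (camera adjusted p = 0.158). Their median was -0.36, and 0.010 with length and GC offsets. RNA quality was not measured by these files, and a lower level of ribosomal protein transcripts after stretch may remain as a hypothesis.

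MHC class II genes were higher in the stretched immune fraction by a median log2 fold change of 1.14. With all immune libraries thinned to the shallowest the median was 1.06. Thinning leaves the expected ratios of abundant genes unchanged, so this cannot decide whether the lower depth of the controls contributed. The receptor-gene reads of immune control 4 are excluded as the whole cause, since the median was 0.92 without that library. A larger share of dendritic cells and macrophages could explain the list, and their other marker genes leave this open: they had a median of 0.15 (quartiles -0.25 to 0.71), with 24 of 42 positive. Monocyte markers, which are not among these, had a median of 0.68, with 11 of 13 positive, and did not pass (camera adjusted p = 0.350). Their reads summed to 12337 to 24097 CPM in the stretched and 5711 to 10208 CPM in the control immune libraries. A change within the cells after stretch is also open.

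In the stromal fraction, 4309 genes had an unadjusted p under 0.05, which 1 of 35 splits, the real one, matched. The highest other split gave 3163, below the 3310 to 4968 found with 1 library left out. This comparison was chosen after the results were seen and sets all libraries against fits with fewer. It therefore leaves chance open for this count, although fewer than 5% of the splits gave as many. In the immune fraction, 0 genes were called with the real grouping and the highest other split gave 97; all 35 splits necessarily give at least 0, so this count says nothing about chance. Its 2467 genes at an unadjusted p under 0.05 were matched by 1 of 35 splits, the real one, but the highest other split, immune control 3 with stretched libraries 1, 7 and 8 against the rest, gave 2462. These counts lie closer together than the 1570 to 3155 genes found with 1 library left out, so chance stays open although fewer than 5% of the splits gave as many. For the difference of effects, where 0 genes were called and the highest other split gave 57, the 100 splits say nothing about chance for the same reason. Its 4232 genes at an unadjusted p under 0.05 were matched by 1 of the 100 splits, the real one, and the highest other gave 3858, while leaving out 1 library gave 3139 to 5745, so chance stays open here too. For the sort, 1 of 35 splits, the real one, gave 7484 genes and the highest other gave 0. The other splits mix the 2 fractions within a group, and 1 in 35 is the smallest share possible here. These counts therefore argue against chance for the sort but do not exclude it.

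Of 128 groups of libraries examined for 1 library far from the others, 8 had one, where chance gives 6.4. Immune control 4 stood apart with 35303 detected genes and 6209 CPM on receptor genes. Stromal control 2 had the lowest receptor-gene value of its group, 17.96 CPM. MHC class II genes summed to 471 CPM in stromal control 4, above the other stromal controls. Neutrophil markers summed to 55662 CPM in immune stretched library 2. Skeletal muscle markers were lowest in immune control 5, at 129 CPM. Ribosomal protein genes were highest in immune control 3, at 24791.5 CPM. *Abhd11os* was highest among the stretched stromal libraries in library 6, at 6.42 CPM. Outside the main measurement, receptor-gene reads reached 424 CPM in stretched stromal library 7 and 208 CPM in library 8, above the stromal controls.

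The stretch effects of the 2 fractions differed by camera in 8 lists, none with an estimated correlation. The median differences, immune minus stromal, were -1.51 for basal keratinocyte markers, -2.77 for hair follicle genes, -1.63 for cell junction genes, -1.34 for blood endothelial markers, -1.32 for lymphatic endothelial markers, 1.05 for fibroblast markers, 2.0 for red blood cell genes and 0.73 for ribosomal protein genes. Without the 3 libraries with receptor-gene reads, 4 of these 8 calls ended. The hair follicle and cell junction medians include members with too few reads to be tested in the immune fraction.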

How the results depend on the processing

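The length and GC offsets and the exclusions of several libraries were chosen after the results were seen. The cause of the changes between settings was not tested. Of the comparisons of gene results with an alternative, 2084 kept direction and side of the threshold, 562 kept direction but no longer passed and 179 kept direction and newly passed; for lists 529 kept both and 124 kept direction but no longer passed. Each of the 45 stromal genes named and called lost its call under 11 to 15 of 21 alternatives. Stromal calls, 800 in the reported fit, were 2312 with DESeq2, 3599 with limma-voom, 2115 without a filter, 1378 with the stricter filter, 0 with glmTreat, 1 with detected genes as a covariate, 0 with all 16 libraries in 1 fit, 4 with length and GC offsets, 0 without stretched libraries 7 and 8 and 3105 without 5 and 6. Immune calls, 0 in the reported fit, were 781 with DESeq2, 888 with limma-voom, 667 with all 16 libraries and 21 without control 4 and stretched library 2. Differing stretch effects, 0 in the reported fit, were 25 with upper-quartile factors, 1625 with DESeq2, 1453 with limma-voom, 3924 without a filter and 120 with the stricter filter. RLE and upper-quartile factors shifted the median difference of all genes from 0.03 to -0.19 and -0.24. Sort calls, 7484 in the reported fit, ranged from 5685 to 9804. Lists called by camera, 8 stromal, 7 immune, 8 for the difference and 23 for the sort, were 0 in each with an estimated correlation; fry called 1, 0, 0 and 24, and camera called 13 stromal lists without stretched libraries 7 and 8. The overlap of calls was 0, and 456 at an unadjusted p under 0.05. Leaving out 1 library at a time gave 0 to 1589 stromal, 0 to 45 immune, 0 to 1495 differing and 6366 to 8566 sort calls, and 7 to 14, 6 to 17, 6 to 15 and 21 to 26 lists. In each of these omissions all tested genes among the 800 kept their direction. They were chosen with all libraries included, so this decides nothing.

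With the title number as a replicate block over all 16 libraries, there were 0 stromal, 0 immune, 2 differing and 7203 sort calls. The stromal values of *Vcl* (-0.050) and *Adamts4* (-0.22) then had the opposite sign. No number occurs in both the stretched and the control group of a fraction. Stretch values under this block therefore rest on a comparison with the other fraction and do not estimate the stretch effect within 1 fraction. The labels do not say whether the numbers pair the samples. Numbers 1, 2, 5 and 6 carry opposite treatments in the 2 fractions, so these cannot mark 1 skin sample sorted into both. For the numbers in general the data did not show pairing, which does not exclude it. Same-numbered libraries of the 2 fractions had deviations correlated at -0.12 to 0.16, 3 of 8 pairs over 0.1. In all, 0 immune libraries matched best to their own number. Simulated genes changed 1.5-fold were recovered in 0% of cases at these depths and spreads in each comparison. Few genes were changed in the simulations, which made 12 to 66 calls. Their adjusted p threshold was therefore stricter than in the sort, with 7484 calls, or the stromal fraction, with 800. The recovered shares do not show what was detectable there.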

Other observations

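The comparison of *Klf4* and *Fosl1* and of the lists below rests on tests fixed before the data were examined; no test here was chosen afterwards.

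In the stretched stromal fraction immediate early genes did not pass camera as a list, with a median log2 fold change of -0.02 and a mean of 0.04 (adjusted p = 0.764), and 0 of 25 members passed the test over all genes, with 2 higher and 2 lower adjusted over the list alone. *Fosl1*, a subunit of AP-1, was 53.2 ± 12.8 against 30.8 ± 5.53 CPM (0.79 ± 0.22, adjusted p = 0.0576), and the transcription factor *Klf4* was 359 ± 99.4 against 652 ± 157 CPM (-0.86 ± 0.26, adjusted p = 0.0691). Heat shock genes (median -0.17, adjusted p = 0.225), chemokines (-0.25, adjusted p = 0.771), YAP/TEAD target genes (0.22, adjusted p = 0.0989) and growth factors of wound repair (0.38, adjusted p = 0.0989) did not pass either. Of 24 hypoxia response genes 1 rose, the histone demethylase *Kdm3a* (1.09 ± 0.22), and 1 fell, the mitochondrial protein *Higd1a* (-0.90 ± 0.23), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.438). Of 23 matrix remodelling genes *Adamts4*, an aggrecanase, rose (0.76 ± 0.18), with 2 adjusted over the list alone (camera adjusted p = 0.0989). The value of *Adamts4* was -0.22 with the title number as a replicate block over all 16 libraries, which rests on immune libraries of the same numbers.

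In the stretched immune fraction, *Fosl1* was 12.7 ± 3.60 against 3.82 ± 1.98 CPM (1.71 ± 0.44, adjusted p = 0.156), the chemokine *Cxcl1* 721 ± 218 against 375 ± 97.3 CPM (0.94 ± 0.34, adjusted p = 0.220) and lysozyme *Lyz2* 9084 ± 1238 against 3895 ± 1766 CPM (1.22 ± 0.48, adjusted p = 0.239). Dendritic cell maturation genes had a median of 0.40, with 21 of 24 positive (camera adjusted p = 0.0532). Macrophage markers (median 0.18, adjusted p = 0.302), T cell markers (0.22, adjusted p = 0.115) and mast cell and basophil markers (0.30, adjusted p = 0.115) did not pass.

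Over the 16 libraries, 26 reads fell on 4 Y-linked genes, and each library held at least 283 reads of *Xist*.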
